A study of Mus musculus with 6 samples.

How the data were processed

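Whole uteri of C57BL/6 female mice aged 10 to 11 weeks were profiled, per the labels' protocols. The mice were ovariectomised and killed 7 days later, and received estradiol (0.05 µg per mouse) or vehicle under the skin at a set time before that. Adhering tissue was trimmed from the uteri, which were pooled before RNA extraction. The labels state 10 mice without saying whether this is per group or in all. Biotin-labelled cRNA from 20 µg of total RNA was hybridised to Affymetrix U74Av2 arrays, on which each gene is read by 1 or more probe sets of short oligonucleotides. The 6 samples are vehicle (injected 24 h before sacrifice) and estradiol at 1, 3, 6, 12 and 24 h, with 1 array each. A further time of 0.5 h that the protocol mentions was not analysed here.

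The deposited table holds, per the submitters' processing notes, the output of the authors' MAS5 software, whose version is not given in the sources used here. Its values are signal intensity on a linear scale, deposited by the authors as 1 value per probe set and array, without detection calls. From the values, each array had been scaled to a common trimmed mean, since the mean after removing the top and bottom 2% was 500.2 to 500.3 on every array. Whether background settings or masks were used is not given in the sources used here. Of 12488 probe sets, 66 Affymetrix control probe sets were left out and 12422 used. The annotation of the array paired 10833 probe sets with 1 gene symbol, 396 with several and 1193 with none, and only the first kind was named. Symbols were updated through the gene identifier, which matched for 10817 probe sets in a RefSeq gene table of the assembly GRCm38.p6. No genome coordinates are given.

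Each array was rescaled to the same 2% trimmed mean over non-control probe sets. Values under the 40th percentile of all scaled values, 142.8, were raised to this floor, and log2 was taken after that. A gene was represented by the probe set with the highest mean log2 signal over the 6 arrays, out of several for 2073 genes. Of 8251 genes named, 6562 were at or above the floor on at least 1 array and 1689 on none. The difference from vehicle was the log2 ratio of the 2 arrays, and a fixed minimum of 2-fold served to count genes. With 1 array per group there is no estimate of error, so no test, p-value or SD between replicates was computed, and the number of arrays limits the precision. A fold against a value below the floor is a lower bound, and none is given where both values lie below it. Between 58.8% and 61.7% of probe sets lay at or above the floor, a share largely set by the choice of its percentile. The 3' to 5' signal ratio of the actin control was 1.13 to 1.25 and that of the Gapdh control 0.793 to 0.892. The spike-in control probe sets had median log2 differences from vehicle of -1.08 at 1 h, -2.28 at 3 h, -0.32 at 6 h, -1.03 at 12 h and -0.58 at 24 h.

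The choices in this paragraph, the main settings and 8 of the 9 alternatives were made before the data were examined. The genes named are, for each time, the 12 with the highest and the 12 with the lowest log2 ratio whose brighter array reached the 60th percentile of all values (352.65), up to 4 genes with the largest difference from each list, the reference genes, and Esr1, Pgr, Igf1, Ltf and C3. Of 33 gene lists with 862 symbols, 724 symbols were found on the array as written, 15 through a synonym and 123 not at all. The lists cover immediate early genes, MAP kinase phosphatases, protein tyrosine phosphatases, the IGF-I pathway, known uterine estrogen targets, steroid receptors and coregulators, Wnt signalling, TGF-beta signalling, growth arrest and p53 targets, G1 cyclins and CDK inhibitors, DNA replication, mitosis, ribosome biogenesis, cytosolic ribosomal proteins, tRNA synthetases and amino acid synthesis, chaperones of the endoplasmic reticulum and of cytosol and mitochondria, cholesterol synthesis, glycolysis, the proteasome, extracellular matrix, interferon-induced genes and reference genes. Marker lists cover uterine epithelium, smooth muscle, stromal fibroblasts, endothelium, macrophages and leukocytes, MHC class II, granulocytes, adipocytes, skeletal muscle and blood. A list with at least 5 measured genes (31 lists) was described by its median log2 ratio, set against 10000 random lists of the same size drawn from 20 bins of mean signal. Medians outside the central range of these, with 2.5% left on each side, are called above or below the random range. A gene below the floor on both arrays entered its list with a log2 ratio of 0. A list median of exactly 0 therefore does not show that the genes were measured as unchanged. This describes the arrays and is not a test of the treatment. Some genes are on more than 1 list: of the estrogen targets, 13 of 29 are on another.

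Where a gene had a second measured probe set, its log2 ratio was compared with that of the brightest, over 1162 genes. This is technical agreement within the same arrays and not a replicate. The Wilson intervals given for it treat genes as independent and measure no spread between mice or pools. The steps were tested on simulated arrays that took their noise from the vehicle and 1 h arrays. In a simulated comparison of 6 h with vehicle over 6310 genes, 50 genes were changed at each fold. They were drawn from genes with a mean signal more than 2-fold above the floor, so recovery near the floor was not tested. Of the genes changed 2-fold, 58% were counted as 2-fold, as were 100% of those changed 3-fold and 4-fold, and 98% of those changed 8-fold. Of 6110 unchanged genes, 15 were counted. The noise was normal, with its spread taken from the central part of the differences, so this count may be too low. A simulated list made only of raised genes lay above the random range, a place fixed by its making, and a list of unchanged genes within it.

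The 8 alternatives planned were scaling to the same median, quantile normalization, the values as deposited, a floor at the 20th or the 60th percentile, the median of all probe sets of a gene, plain probe sets alone (those with names that carry no mark of possible cross-hybridisation), and the mean of the vehicle and 1 h arrays as the reference from 3 h on. The array labelled 3 h was left out in 1 further alternative, chosen after its values were seen. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.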

Results

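Gene expression was measured in whole uteri of ovariectomised female mice that received a single injection of estradiol, the main ovarian estrogen, or of vehicle. Removing the ovaries takes away most circulating estrogen, so the injected hormone acts on a regressed organ. The groups profiled, with 1 array of pooled RNA in each, were vehicle, and 1, 3, 6, 12 and 24 h after 0.05 µg of estradiol per mouse. The comparisons ask which uterine genes differ from vehicle after estradiol and in what order. The vehicle array was taken 24 h after injection, so only the 24 h comparison is matched in time since injection. At the earlier times, an effect of the injection itself cannot be told apart from one of estradiol. No group had a replicate array, so no difference could be set against the spread between replicates, none was tested, and each comparison describes 2 arrays. On each array, 58.8% to 61.7% of the probe sets lay at or above the detection floor of 142.8 signal units, and 6562 of the 8251 named genes did so on at least 1 array. Where the dimmer array lay below the floor, the fold is given against the floor as "at least".

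The number of genes at least 2-fold away from vehicle was smallest at 1 h. At 1 h, 56 genes were higher and 23 lower, counts that depended on the floor, with 258 and 161 under the lower floor and 24 and 5 under the higher. At 6 h, 416 were higher and 548 lower, at 12 h 404 and 455, and at 24 h 224 and 232. On the array labelled 3 h, 706 were higher and 805 lower. Which direction held more genes depended on the scaling: with the arrays scaled to the same median, 497 were higher and 444 lower at 6 h, 455 and 395 at 12 h, 234 and 220 at 24 h, and 846 and 652 on the array labelled 3 h. In 100 simulated comparisons without any effect, with the spread between the vehicle and 1 h arrays as the noise, a mean of 19.98 genes were 2-fold higher and 18.97 lower, with at most 32 in either direction. This noise includes any response at 1 h, so it is no yardstick for the 1 h counts, and for later times it rests on a single pair of pools. Its spread was taken after flooring and drawn from a normal distribution, so the simulated counts may be too low. The arrays for 1, 6, 12 and 24 h and the vehicle array correlated across probe sets at Spearman's rho of 0.929 to 0.968 over their 10 pairs. The array labelled 3 h stood apart from all 5, at 0.843 to 0.857.

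One hour after estradiol, the genes with the highest folds included early response genes and known uterine estrogen targets. Gadd45g, a growth arrest and DNA damage response gene, was 23.6-fold higher, with a signal of 407 in vehicle and 9583 at 1 h. Plk2, a polo-like kinase, was 8.06-fold higher, Adm, which encodes the vasodilator peptide adrenomedullin, 5.75-fold, and Fos, a subunit of the AP-1 transcription factor, 4.82-fold. Inhbb, the activin beta B subunit, was at least 4.82-fold higher. Errfi1, a feedback inhibitor of the epidermal growth factor receptor, was 4.35-fold higher, the Ras-related gene Rasd1 4.20-fold, the cytokine signalling suppressor Socs1 3.20-fold and Spsb1 3.22-fold. The other genes among the 12 highest were Snrp1c-ps2, a pseudogene name, at 6.88-fold, the fatty acid binding protein gene Fabp5 at least 3.50-fold and Prp2 at 3.36-fold.

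As groups, 6 of the 25 immediate early genes measured were at least 2-fold higher at 1 h and none lower, with a median log2 ratio of 0.41, above the range of random lists. Of 29 known uterine estrogen targets, 4 were higher and none lower (median 0.34), also above that range. The 17 G1 cyclins and CDK inhibitors had a median of 0.19, above the range with no member at 2-fold. The 14 cytosolic ribosomal protein genes (-0.34) and the 22 uterine epithelium markers (-0.13) lay below it, again with no member at 2-fold. These last 3 placements, unlike the first 2, were lost under at least 1 other processing choice. The other 26 lists lay within the range.

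Of the 23 genes lower at 1 h, none of the 31 lists held more than 1, while 2 were on a list of pancreatic acinar genes made after the values were seen. Fancc, a Fanconi anaemia DNA repair gene, was 4.50-fold lower. The digestive protease genes Prss2 and Cela2a were at least 3.46-fold and at least 3.00-fold lower, and Pomc, the precursor of adrenocorticotropic hormone, at least 3.46-fold. The beta-actin gene Actb was 3.22-fold lower by its brightest probe set, from 2080 to 646, while the control probe sets for beta-actin differed from vehicle by a factor of 0.779 to 0.840. Kcnn1 and Kat2a were at least 3.19-fold and 2.77-fold lower, Chst3 had a log2 ratio of -1.32 or less, and Asb6, Idnk, Pccb and Prcc were 2.70-fold, 2.57-fold, 2.57-fold and 2.53-fold lower. With the median of all probe sets of a gene in place of the brightest, the log2 ratio of Fos was 1.14, that of Fancc -1.09 and that of Prcc -0.67. Only 6 of the 19 genes at 2-fold that had a second measured probe set (31.6%, Wilson 95% interval 15.4% to 54.0%) had it in the same direction at 1.5-fold or more.

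At 6 h the uterus showed higher signal for genes of ribosome biogenesis, protein folding, tRNA charging and cholesterol synthesis, together with estrogen targets. Ramp3, a partner of the adrenomedullin receptor, was 11.2-fold higher, Idi1, an isomerase of the cholesterol pathway, 11.8-fold, and Inhbb at least 25.2-fold. Krt6a, a keratin of stratified and hyperproliferative epithelium, was 21.6-fold higher, from 754 to 16315, and Sprr2f, a small proline-rich protein of epithelium, 8.07-fold. Gadd45g and Plk2 were again far above vehicle, at 20.2-fold and 9.80-fold. The spermidine synthase gene Srm was 8.13-fold higher, the arginine deiminase gene Padi1 9.18-fold, the tyrosine phosphatase gene Ptpn5 at least 10.1-fold, the adenylate kinase gene Ak1 at least 8.45-fold and Bcl3 at least 7.80-fold.

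Of 35 ribosome biogenesis genes, 22 were at least 2-fold higher at 6 h and none lower, with a median log2 ratio of 1.24. The nucleolar genes Ddx21, Nop56, Nop58 and Nop2 were 5.75-fold, 5.50-fold, 5.15-fold and 4.79-fold higher. The 14 cytosolic ribosomal protein genes themselves had a median of -0.27, within the random range. Of 28 tRNA synthetase and amino acid synthesis genes, 17 were higher (median 1.11), led by the mitochondrial folate enzyme Mthfd2 at 7.70-fold. Of 22 endoplasmic reticulum chaperone genes, 15 were higher (median 1.08), with Manf at 4.89-fold and Creld2 at 4.69-fold. Of 27 cytosolic and mitochondrial chaperone genes, 12 were higher (median 0.88), with Hsph1 at 4.67-fold and the chaperonin subunits Cct6a and Cct3 at 4.16-fold and 3.96-fold. Of 29 proteasome genes, 8 were higher (median 0.71), among them Psmd14 at 2.96-fold and Psme3 at 2.75-fold. None of the genes on these 5 lists was 2-fold lower. Of 16 cholesterol synthesis genes, 7 were higher and none lower (median 0.73). Besides Idi1, Sqle was 7.30-fold, Fdps 5.10-fold and Msmo1 at least 5.64-fold higher.

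Known estrogen targets stood at a median of 0.88 at 6 h, with 14 of 29 at least 2-fold higher and 1 lower. The progesterone receptor gene Pgr was 5.44-fold higher, from 160 to 870. The cell cycle inhibitor gene Cdkn1a was 5.17-fold higher by its brightest probe set, but its other probe set had a log2 ratio of -0.11. Immediate early genes were again above the random range (0.46), with 8 of 25 higher and 3 lower. DNA replication genes lay above it at a median of 0.29, with 5 of 31 higher, among them Rrm2, a ribonucleotide reductase subunit, at least 3.12-fold. Mitosis genes had a median of 0.00, with 2 of 34 higher and 1 lower. The middle members of this list lay below the floor on both arrays, so that median does not show them unchanged. The estrogen targets and DNA replication genes stayed above the range under the other processing choices. The immediate early genes lay within it when the mean of the vehicle and 1 h arrays was the reference (0.14). As a list they were already above vehicle at 1 h, so that reference lowers their median by construction.

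Among the 12 genes furthest below vehicle at 6 h, Apcdd1, a Wnt inhibitor of the cell surface, was 9.47-fold lower and the secreted Wnt antagonist Sfrp2 7.23-fold. Cyclin G2 (Ccng2), linked to cell cycle arrest, was at least 9.23-fold lower, the stress-inducible Sesn1 7.02-fold and the Myc antagonist Mxi1 at least 6.34-fold. The adaptor gene Gab1 was 6.99-fold lower. The remaining genes among these 12 were Mmp11 (at least 7.58-fold), Sash1 (7.27-fold), Ypel3 (6.68-fold), the digestive protease gene Ctrb1 (6.64-fold), the Wnt pathway ligand gene Ndp (at least 6.35-fold) and Ngef (at least 6.26-fold). Outside them, the IGF-I receptor gene Igf1r was 6.20-fold lower, from 2912 to 470. Growth arrest and p53 targets as a list had 4 members higher and 4 lower (median -0.29), within the random range. The medians of Wnt signalling (-0.34, 3 of 20 lower and 1 higher) and of TGF-beta, BMP and activin signalling (-0.34, 3 of 26 lower and 1 higher) lay below the random range, and each lost that place under a different floor.

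Markers of stromal fibroblasts were lower at 6 h at a median of -0.73, with 8 of 21 at least 2-fold lower and 1 higher. Wt1, a transcription factor of stroma, was 3.07-fold lower, whereas Twist2 was 2.22-fold higher and Hoxa11 1.23-fold lower. Adipocyte markers had a median of -0.78 and MHC class II genes of -0.52, each with 2 members at 2-fold lower. The MHC class II placement was lost under 4 other processing choices, and with the same median its members H2-DMb1 and H2-Eb1 stood at -0.92 and -0.91. Interferon-induced genes had a median of -0.82, with 7 of 18 lower. The guanylate-binding protein gene Gbp3 was 4.49-fold and the GTPase gene Iigp1 3.56-fold lower. On the same array, markers of smooth muscle (0.00), uterine epithelium (-0.15), endothelium (-0.13) and macrophages and leukocytes (-0.18) had medians within the random range. The middle smooth muscle marker lay below the floor on both arrays. With the median of all probe sets of a gene, 11 of the 121 named genes at 2-fold at 6 h were under 2-fold, among them Fdps at a log2 ratio of 0.79, and Cdkn1a stood at 1.13. With the floor at the 60th percentile 25 of the 121 were under 2-fold, and with the mean of the vehicle and 1 h arrays as reference 21. A second probe set of the gene was in the same direction at 1.5-fold or more for 93 of 180 genes (51.7%, Wilson 95% interval 44.4% to 58.9%).

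**Figure D1:**
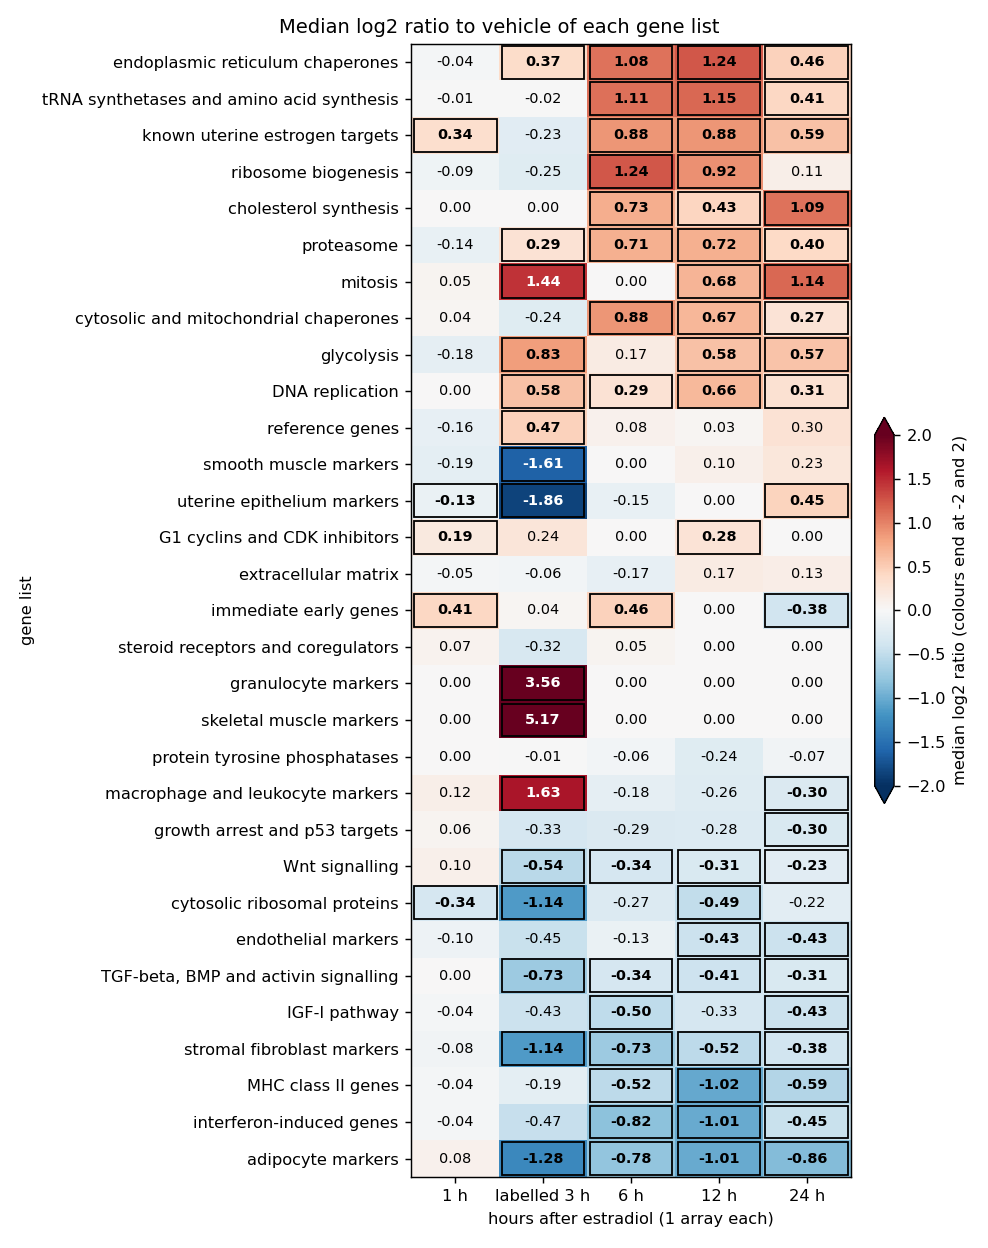
Median log2 ratio to vehicle of the measured genes of each of 31 lists (vertical axis) on each estradiol array (horizontal axis, hours after injection), with boxed bold values outside the central range of 10000 random lists. Ribosome biogenesis stands at 1.24 at 6 h and 0.11 at 24 h, mitosis at 0.00 and 1.14, and skeletal muscle markers at 5.17 on the array labelled 3 h and 0.00 on the others. A median of 0.00 can come from genes below the floor on both arrays.

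At 12 h the biosynthetic groups and DNA replication genes were still above vehicle, mitosis genes were now above it too, and the 3 highest folds were those of keratins. Krt6a was 26.2-fold higher, Krt6b 19.4-fold and Krt16 at least 18.7-fold, all 3 being keratins of activated stratified epithelium, with Sprr2f at 11.5-fold, the desmosomal cadherin gene Dsc2 at least 8.27-fold and the epithelial 14-3-3 protein gene Sfn at 7.03-fold. Inhbb was at least 13.6-fold higher, Fkbp11, a prolyl isomerase of the secretory pathway, at least 9.48-fold, and Mthfd2 8.19-fold. Fabp5, Ak1 and the serpin gene Serpinb2 were at least 6.51-fold, 6.36-fold and 5.95-fold higher.

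Endoplasmic reticulum chaperones had their highest median at 12 h (1.24, 14 of 22 higher), with the disulfide isomerase genes Pdia4 at 4.65-fold and Pdia3 at 4.63-fold. The tRNA and amino acid list stood at 1.15 (15 of 28), with Psat1, an enzyme of serine synthesis, at 3.56-fold and the cysteinyl-tRNA synthetase gene Cars at least 4.39-fold. Ribosome biogenesis (0.92, 15 of 35), the proteasome (0.72, 7 of 29), cytosolic and mitochondrial chaperones (0.67, 8 of 27) and cholesterol synthesis (0.43, 5 of 16) remained above the random range, and no member of these 6 lists was 2-fold lower. DNA replication genes reached a median of 0.66 with 8 of 31 higher, among them Uhrf1, needed for maintenance of DNA methylation, at 3.85-fold and the sliding clamp gene Pcna at 2.52-fold. Mitosis genes reached 0.68, with 11 of 34 higher, among them the proliferation marker Mki67 at 2.47-fold. With the median of all its probe sets, Mki67 was under 2-fold at 12 h, at a log2 ratio of 0.89. Estrogen targets stood at 0.88 with 14 of 29 higher and none lower, and glycolysis genes at 0.58 with 4 of 13 higher and 1 lower, the glucose transporter gene Slc2a1 at 3.69-fold higher and the hexokinase gene Hk1 at 2.60-fold lower.

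The lists for MHC class II, interferon response, stroma and adipocytes lay below the random range at 12 h under every processing choice run. The 9 MHC class II genes had a median of -1.02 with 5 lower, among them H2-Eb1 at 2.91-fold and H2-Aa at 2.70-fold, while markers of macrophages and leukocytes had a median of -0.26, within the random range. Interferon-induced genes stood at -1.01 (9 of 18 lower), with Iigp1 at 4.25-fold. Stromal markers stood at -0.52 (7 of 21). Endothelial markers stood at -0.43 (4 of 19), with the tight junction gene Cldn5 4.28-fold and the von Willebrand factor gene Vwf at least 4.37-fold lower. Adipocyte markers had a median of -1.01 with 7 of 14 lower, among them the hormone gene Retn at 2.57-fold and the carbonic anhydrase gene Car3 at 3.08-fold. TGF-beta signalling (-0.41), Wnt signalling (-0.31) and cytosolic ribosomal proteins (-0.49, with Rpl22 2.02-fold lower) also lay below the random range, and the G1 cyclins and CDK inhibitors above it (0.28), although the inhibitor gene Cdkn1c was 5.73-fold lower. The placements of endothelial markers, cytosolic ribosomal proteins, G1 cyclins and CDK inhibitors, and Wnt signalling at 12 h were each lost under at least 1 other processing choice.

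The genes furthest below vehicle at 12 h included Igfbp3, a carrier of IGF-I, at 19.7-fold lower (6996 to 356), the methyltransferase gene Inmt at 11.8-fold, Sfrp2 at 8.85-fold and tenascin X (Tnxb) at a log2 ratio of -3.07. The cathepsin gene Ctsf was at least 8.82-fold lower, Itih5 6.95-fold, Ccng2 6.83-fold, Sun2 6.64-fold, Txndc16 at least 6.79-fold and the potassium channel gene Kcnj8 at least 6.71-fold. Nr1d2, a repressor of the circadian clock, was 6.09-fold lower. Txnip, a thioredoxin-binding protein regulated by glucose, was 6.95-fold lower by its brightest probe set, but its other probe set was 1.22-fold higher. With the median of all probe sets of a gene, 21 of the 127 named genes at 2-fold at 12 h were under 2-fold. With the floor at the 60th percentile 25 were, and with the mean of the vehicle and 1 h arrays as reference 15. A second probe set was in the same direction at 1.5-fold or more for 87 of 163 genes (53.4%, Wilson 95% interval 45.7% to 60.9%), and in the opposite direction at that fold for 3.

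At 24 h the 3 highest folds were again those of keratins. No list of keratinising epithelium was set beforehand, so that grouping comes from the values themselves. Krt16 was at least 77.7-fold higher, with a signal of 11094, Krt6b 47.4-fold (25865) and Krt6a 41.6-fold (31370). The small proline-rich gene Sprr1a was 25.6-fold higher, Sprr3 at least 17.2-fold and Sprr2c-ps at least 13.6-fold. Krt17 was 16.9-fold and Krt10, a keratin of differentiated epidermis, 15.1-fold higher, with Krtdap, expressed in differentiating keratinocytes, at least 18.0-fold. The connexin gene Gjb2 was 17.4-fold higher, the cell surface antigen gene Psca 18.6-fold and Fabp5 at least 13.9-fold. The list of uterine epithelium markers as a whole had a median of 0.45 at 24 h, above the random range, with 5 of 22 higher, among them Sfn at 12.3-fold and the desmosomal gene Dsp at 3.45-fold, while the simple epithelial keratins Krt8 and Krt19 were 1.32-fold and 1.48-fold higher.

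Mitosis genes were at their highest median outside the array labelled 3 h, 1.14, with 21 of 34 at least 2-fold higher and none lower. Mki67 was 3.17-fold higher, the kinesin gene Kif20a at least 3.16-fold, Cks2 2.61-fold and the topoisomerase gene Top2a 2.24-fold. DNA replication genes stood at 0.31, with 5 of 31 higher. Cholesterol synthesis genes stood at 1.09, with 9 of 16 higher, among them Idi1 at 7.86-fold, Fdps at 7.85-fold and Sqle at 6.10-fold. Glycolysis genes stood at 0.57, with 4 of 13 higher, among them Slc2a1 at 4.08-fold. Endoplasmic reticulum chaperones (0.46), the tRNA and amino acid list (0.41), the proteasome (0.40) and the cytosolic and mitochondrial chaperones (0.27) were closer to vehicle than at 12 h though still above the random range, and ribosome biogenesis (0.11, 1 of 35 higher) was within it. Estrogen targets stood at 0.59, with 9 of 29 higher and 1 lower, among them the siderophore-binding protein gene Lcn2 at 11.0-fold.

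Furthest below vehicle at 24 h were Inmt, with a signal of 2065 in vehicle and 313 at 24 h, Igfbp3 at 6.26-fold lower and the testis protease gene Adam5 at 5.88-fold. The leptin receptor gene Lepr was at least 5.73-fold lower, Cpxm2 at least 4.52-fold, the water channel gene Aqp1 4.51-fold, Tgfbi 4.39-fold, 6330403K07Rik 4.32-fold and the cholesterol exporter gene Abca1 4.28-fold. Car3, Ccn2 and the lipoprotein lipase gene Lpl were 3.85-fold, 3.84-fold and 3.60-fold lower. Adipocyte markers stood at -0.86 (5 of 14 lower), MHC class II genes at -0.59 (4 of 9), interferon-induced genes at -0.45 (no member at 2-fold), endothelial markers at -0.43 (3 of 19) and stromal markers at -0.38 (3 of 21). TGF-beta, BMP and activin signalling stood at -0.31. Immediate early genes (-0.38), growth arrest and p53 targets (-0.30), macrophage and leukocyte markers (-0.30) and Wnt signalling (-0.23) also lay below the random range, but each lost that place under other processing choices. With the median of all probe sets of a gene, 11 of the 92 named genes at 2-fold at 24 h were under 2-fold, among them Dsp at a log2 ratio of 0.89, while Krt10 stood at 1.96. With plain probe sets alone Kif20a stood at 0.61 and Adam5 at 0.00. With the floor at the 60th percentile 19 of the 92 were under 2-fold, and with the mean of the vehicle and 1 h arrays as reference 17. A second probe set was in the same direction at 1.5-fold or more for 35 of 90 genes (38.9%, Wilson 95% interval 29.5% to 49.2%), and in the opposite direction at that fold for 1.

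**Figure D2:**
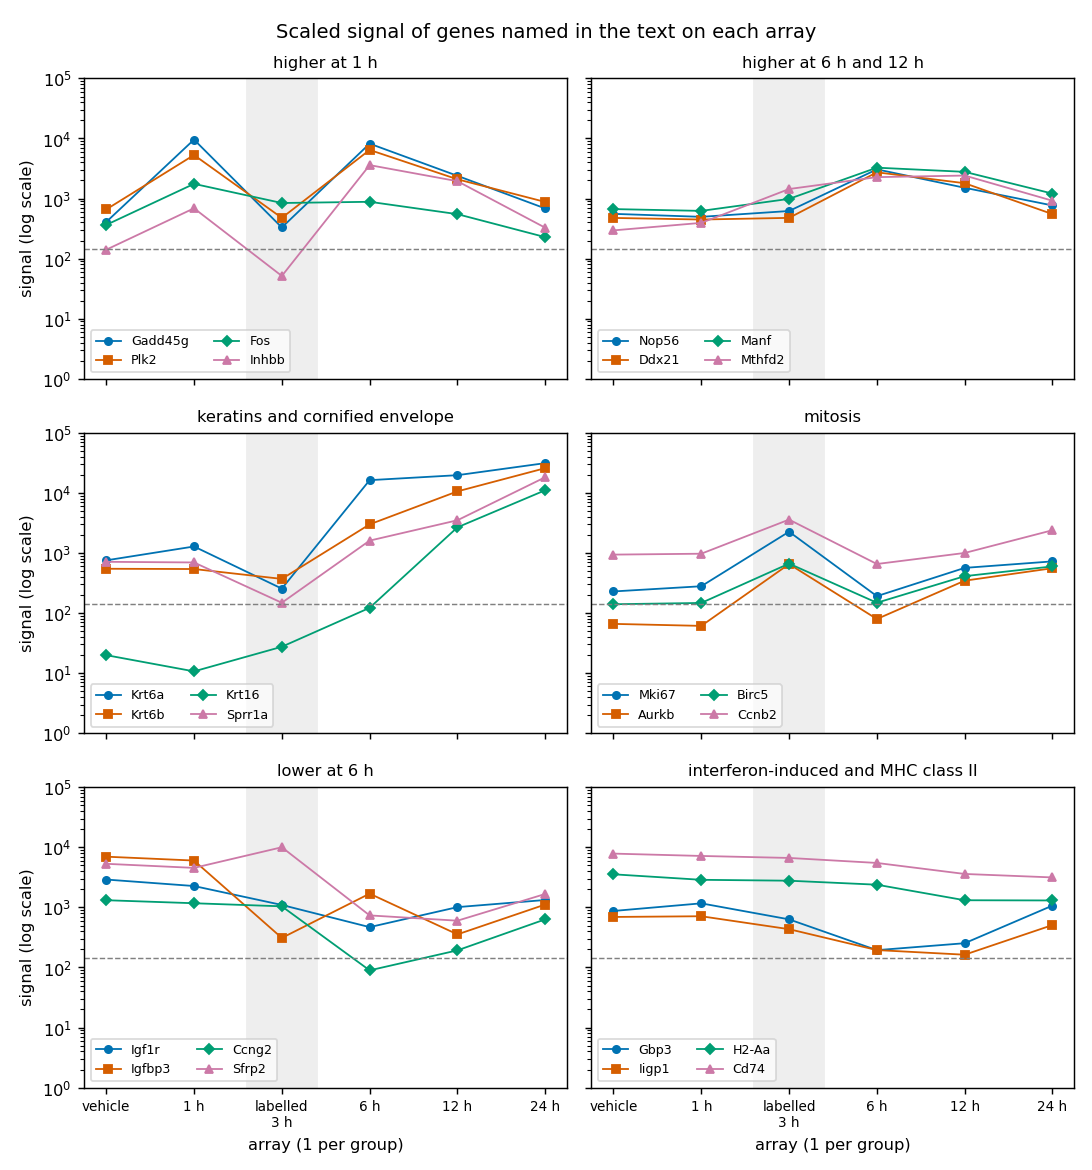
Scaled signal (vertical axis, log scale) of 24 genes in 6 panels on the 6 arrays (horizontal axis), with the floor of 142.8 as a dashed line and the array labelled 3 h shaded. Gadd45g stands at 9583 at 1 h and 8211 at 6 h, Krt16 at 11094 at 24 h, and Igfbp3 at 6996 in vehicle and 356 at 12 h; Aurkb, Birc5 and Ccnb2 were added after their values were seen.

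The array labelled 3 h showed little of the signal that marks the uterus on the other arrays. Hoxa11, a homeobox gene of the uterine stroma, was at least 18.6-fold lower than in vehicle (2662 to 14.6), and the epithelial genes Wfdc2, Krt8 and Krt19 were at least 38.3-fold, 15.4-fold and 15.4-fold lower, with Krt18 down from 2285 to 64.9. The smooth muscle genes Acta2 and Cnn1 were 15.1-fold and at least 18.3-fold lower, and Myh11 stood at 243 against 9706. By its brightest probe set, the estrogen receptor gene Esr1 was at least 3.69-fold lower, from 527 to 25.2. This probe set stood between 457 and 582 on the other 4 estradiol arrays. The lists for uterine epithelium (-1.86, 17 of 22 lower), smooth muscle (-1.61, 10 of 15) and stroma (-1.14, 12 of 21) all lay below the random range.

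In their place, skeletal muscle, granulocyte and red cell genes were high on this array. All 15 skeletal muscle markers were at least 2-fold higher, with a median log2 ratio of 5.17, led by the calcium pump gene Atp2a1 at 132-fold and the myosin genes Myh4 and Myh1 at least 99.5-fold and 78.0-fold. Of 17 granulocyte markers, 13 were higher (median 3.56), with S100a8 at least 155-fold, S100a9 at least 120-fold and Ngp at least 119-fold. The haemoglobin genes Hba-a1 and Hbb-b2 were 9.84-fold and 24.5-fold higher, and the red cell genes Alas2 and Slc4a1 at least 27.2-fold and 32.7-fold. Macrophage and leukocyte markers stood at 1.63 (15 of 25 higher), mitosis genes at 1.44 (22 of 34), glycolysis genes at 0.83, DNA replication genes at 0.58, the reference genes at 0.47, endoplasmic reticulum chaperones at 0.37 and the proteasome at 0.29, all above the random range. Adipocyte markers (-1.28), cytosolic ribosomal proteins (-1.14), TGF-beta signalling (-0.73) and Wnt signalling (-0.54) lay below it, Wnt signalling not under a higher floor. A second probe set was in the same direction at 1.5-fold or more for 175 of 316 genes (55.4%, Wilson 95% interval 49.9% to 60.8%), and in the opposite direction at that fold for 6. Under a lower floor the brightest probe set of Myh4 was another, with a log2 ratio of -1.07.

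Xist, the transcript that coats the inactive X chromosome of female cells, was at least 10.7-fold lower on the array labelled 3 h, with a signal of 26.9 against 1533 in vehicle. Xist and the Y-linked Eif2s3y were examined after the other markers had been seen. Eif2s3y had a signal of 401 on this array and of 39.1 or less on the other 5. Of 40 genes at least 2-fold higher or lower in the same direction at 1 h and at 6 h, 27 (67.5%) lay in that direction on this array. All these ratios share the vehicle array, which adds agreement, and no baseline for this share was computed. Gadd45g, at 23.6-fold and 20.2-fold on the neighbouring arrays, was 1.23-fold lower, and Pgr was below the floor. The direction of any gene at 3 h therefore rests on an array whose markers differ from those of the other 5. Without it, 6326 genes are measured.

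**Figure D3:**
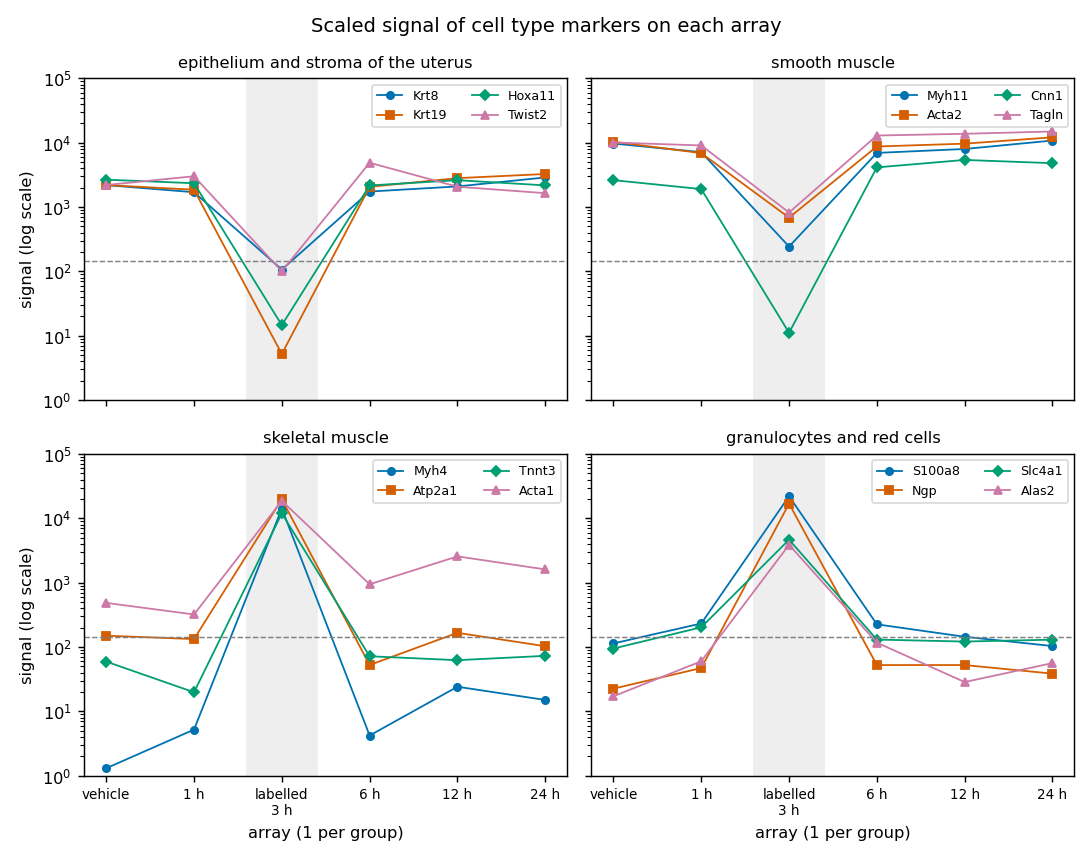
Scaled signal (vertical axis, log scale) of 16 marker genes in 4 panels on the 6 arrays (horizontal axis), with the floor of 142.8 as a dashed line and the array labelled 3 h shaded. On that array Hoxa11 stands at 14.6 and Myh11 at 243, while S100a8 stands at 22112 and Atp2a1 at 19767, against 114 and 150 in vehicle.

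Over all 5 times, 2403 genes (36.6% of those measured) were at least 2-fold from vehicle at some time, 96 of them in both directions. Without the array labelled 3 h the count was 1417 (21.6% of the same 6562 genes), with 5 in both directions. The extracellular matrix list had medians of -0.05, -0.06, -0.17, 0.17 and 0.13 at the 5 times, all within the random range, with members in both directions. By the time of the largest difference, and without that array, 31 genes were highest relative to vehicle at 1 h, 272 at 6 h, 205 at 12 h and 156 at 24 h, and 16, 399, 245 and 93 were lowest at these times. With it, 631 genes had their largest positive and 686 their largest negative difference at 3 h. Of the genes higher at 6 h, 267 of 416 (64.2%) were also higher at 12 h, where independent lists would share 25.6. Of the genes lower at 6 h, 320 of 548 (58.4%) were also lower at 12 h, against 38.0. From 12 h to 24 h, 128 higher and 150 lower genes were shared, against 13.8 and 16.1 for independent lists. At 1 h and 6 h, 27 higher and 13 lower genes were shared, against 3.55 and 1.92. Every array is compared with the same vehicle array, which adds shared genes. Simulated arrays without effect shared 1.81 higher and 2.80 lower genes between 6 h and 12 h, 1.59 and 2.81 between 12 h and 24 h, and 1.67 and 2.89 between 1 h and 6 h, but their lists held means of 19.98 and 18.97 genes, so these values are no baseline for the longer lists.

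Between successive estradiol arrays, the 6 h and 12 h arrays differed least, though more than vehicle and 1 h. From 6 h to 12 h, 108 genes were at least 2-fold higher and 87 lower, and from 12 h to 24 h 189 and 162. From 1 h to 6 h, 436 were higher and 479 lower. Steps into and out of the array labelled 3 h gave 711 higher and 838 lower genes from 1 h, and 792 higher and 889 lower genes to 6 h. That array also held 425 genes at least 2-fold above every other array and 239 below every other. The 24 h array held 42 above and 3 below, the 6 h array 19 and 24, the vehicle array 4 and 4, the 12 h array 1 and 2, and the 1 h array 1 and 1. The 4 genes highest in vehicle were Prss2, Pklr, Cela2a and Irs2, of which Pklr and Irs2 were named after their values were seen.

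Genes of the growth factor and phosphatase groups, which are themes of this study, were looked at as lists of their own, so their direction is not independent evidence. Of the 21 IGF-I pathway genes measured, 6 were at least 2-fold lower and 2 higher at 6 h (median -0.50), 6 lower and 1 higher at 12 h (-0.33) and 5 lower and 1 higher at 24 h (-0.43). The 6 h and 24 h medians lay below the random range, though not under every floor. Besides Igf1r and Igfbp3, the binding protein gene Igfbp6 was 2.79-fold lower at 12 h and Foxo3, a transcription factor restrained by insulin signalling, 3.69-fold lower at 6 h. Igf1 itself was 1.57-fold higher at 6 h by its brightest probe set, from 1234 to 1931, and 10.1-fold higher by its other, from 337 to 3392, so its fold depended on the probe set. The 24 protein tyrosine phosphatase genes had medians between -0.24 and 0.00 at all 5 times, within the random range. Ptpn13 was 3.76-fold lower at 6 h and 2.92-fold lower at 12 h. Ptpn5, at least 10.1-fold higher at 6 h and at least 3.75-fold at 12 h, was not on this list. Only 4 of the MAP kinase phosphatases were measured, too few for a median. Dusp1 was 2.13-fold higher at 1 h, from 732 to 1560, and stood at 1101 at 6 h. Dusp2, Dusp6 and Dusp16 were under 2-fold at every time.

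The classical targets Esr1, Pgr, Ltf and Igf1 were followed at every time whatever their values. By its brightest probe set, Esr1 differed from vehicle by 1.15-fold or less at 1, 6, 12 and 24 h. Its other, dimmer probe sets differed more. Another probe set was 1.82-fold higher at 24 h, from 149 to 271. Others fell from 243 to 82.2 and from 242 to 72.6 at 6 h, both to below the floor. Pgr was 1.78-fold higher at 1 h, 5.44-fold at 6 h, 3.77-fold at 12 h and 1.76-fold at 24 h. Ltf, which encodes the secretory protein lactoferrin, was 1.28-fold higher at 1 h and then 1.36-fold, 1.90-fold and 1.29-fold lower at 6, 12 and 24 h, and 4.15-fold higher on the array labelled 3 h, where the markers of granulocytes, which also make lactoferrin, stood at a median of 3.56. Complement C3 was not named on the array. The 15 steroid receptor and coregulator genes had medians of 0.07, -0.32, 0.05, 0.00 and 0.00 at the 5 times, all within the random range, with Cited2 3.20-fold lower and Fkbp5 2.33-fold higher at 6 h. The 11 reference genes lay within the range at all times except on the array labelled 3 h. Among them Polr2a differed by 1.27-fold or less at all 5 times, while the transferrin receptor gene Tfrc was 2.67-fold higher at 6 h and Pgk1 2.45-fold higher at 24 h. Tfrc at 6 h stood at a log2 ratio of 0.68 with plain probe sets alone, and at 0.97 with the mean of the vehicle and 1 h arrays as reference. The beta-actin gene Actb stood at -1.69 at 1 h, -1.01 at 6 h, -1.02 at 12 h and -0.26 at 24 h. Its control probe sets differed from vehicle by a factor of 1.12 to 1.23 at 6 h. Of the 155 entries of 31 lists at 5 times, 42 lay above the random range and 35 below it, and without the array labelled 3 h 33 and 28 of 124 did so.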

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

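Of the explanations weighed here, the test on males was written before its values were computed, while those on another tissue, on a minor carry-over and on a response of the uterus were chosen only after the result was seen. The array labelled 3 h carried skeletal muscle, granulocyte and bone genes and little uterine signal; the 6 bone markers, a list made after the values were seen, had a median log2 ratio of 3.85, with Mmp13 at a signal of 8102 and Ibsp at 3715. A minor carry-over of muscle, marrow or bone into a uterine pool is argued against by the 22 uterine epithelium markers, since a minor addition would leave most of their signal. With the floor, they stood at a median of 24.3% of their mean over the other arrays, an upper bound where the signal lay below the floor. Without the floor, the median was 9.29% (quartiles 3.51% and 16.2%), which rests partly on signals below it. A response of the uterus at 3 h is argued against by Xist, at a log2 ratio of -3.42 here and between -0.30 and 0.30 on the other 4 estradiol arrays, because Xist is made by female cells of any tissue. RNA mostly of another tissue under this label remains a possible explanation, with the skeletal muscle markers at 5.17, but the tables do not show how it came about or which tissue it was. Whether the RNA came from males was not decided by the test written beforehand. The Y-linked difference was at least 1.49, a bound against the floor, and the floor kept it under the value that the test asked for. It rests on Eif2s3y, the only measured gene of the 3 named on the array. The signals of Eif2s3y and the low Xist both go with male RNA, but each is a single gene, so other causes cannot be told apart.

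The bound for the explanation by squamous tissue was written before its value was computed. The explanation by a larger share of epithelium was chosen only after the result was seen. Keratinisation genes, listed after their values were seen, had medians of 0.86 at 6 h, 2.35 at 12 h and 4.09 at 24 h, and all 16 were at least 2-fold higher at 24 h, the lowest at 2.92. A larger share of epithelium of every kind is argued against as the main source, because the uterine epithelium markers stood at 0.45. More cervix or vagina in the later pools cannot be told apart from a response within the uterus: the 7 measured basal squamous markers stood at 0.44 at 24 h, more than 2 log2 units below the keratinisation genes, the bound set beforehand against this explanation. That bound does not decide, because these markers already had signals of 265 to 942 in vehicle, which would hide a small added share. This condition on the vehicle signal was not part of what was written beforehand. A direct response of uterine epithelium to estradiol stays open and was not tested.

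The following differences were seen and not tested. Immediate early genes had a median of 0.46 at 6 h and -0.38 at 24 h. Uterine epithelium markers stood at -1.86 on the array labelled 3 h and at 0.45 at 24 h. Macrophage and leukocyte markers stood at 1.63 on the array labelled 3 h and at -0.30 at 24 h. Among the control probe sets, which entered no count of genes, the middle Gapdh probe set was 2.03-fold higher on the array labelled 3 h. The 3' transferrin receptor control was at least 3.44-fold higher on that array and at least 2.67-fold higher at 6 h.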

How the results depend on the processing

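No paired analysis was possible because each group has 1 array. The share of 2-fold genes with a second probe set in the same direction at 1.5-fold or more was followed over 5 alternatives. These did not include the probe set and reference ones. The share ran from 21.9% to 40% at 1 h, 46.4% to 56.4% at 6 h and 47.8% to 55.2% at 12 h. A lower floor passes more genes and a higher floor fewer by construction. The reference that includes the 1 h array, also by construction, lowers the ratio of genes higher at 1 h and raises that of genes lower then. For the other shifts the cause was not tested. Leaving out the array labelled 3 h was chosen only after its values were seen. Counts below are of genes at least 2-fold higher or lower.

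With the floor at the 20th percentile, the counts against vehicle were 258 higher and 161 lower at 1 h, 838 lower at 6 h, 685 lower at 12 h, and 452 higher and 441 lower at 24 h. Between times, 1295 genes were lower at 3 h than at 1 h and 823 lower at 6 h than at 1 h. From 6 h to 12 h, 293 were higher and 217 lower, and from 12 h to 24 h 395 and 296. The largest difference fell at 1 h for 131 higher and 81 lower genes and at 24 h for 208 and 136. Genes apart from every other array numbered 22 higher and 18 lower in vehicle, 18 and 14 at 1 h, 382 lower at 3 h, 70 lower at 6 h, 3 higher and 20 lower at 12 h, and 64 higher and 26 lower at 24 h. Myh4 on the array labelled 3 h stood at -1.07, read by another probe set.

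With the floor at the 60th percentile, the counts against vehicle were 24 higher and 5 lower at 1 h, 467 lower at 3 h, 308 lower at 6 h, 273 lower at 12 h, and 136 higher and 139 lower at 24 h. Between times, 452 genes were lower at 3 h than at 1 h, 495 higher at 6 h than at 3 h, and 256 lower at 6 h than at 1 h. From 6 h to 12 h, 41 were higher and 46 lower, and from 12 h to 24 h 94 and 91. The largest difference fell at 1 h for 11 higher and 4 lower genes, at 3 h for 399 lower, at 6 h for 159 lower, at 12 h for 92 lower, and at 24 h for 70 higher and 36 lower. Genes apart from every other array numbered 0 higher in vehicle, 0 lower at 1 h, 118 lower at 3 h, 11 higher and 6 lower at 6 h, 0 lower at 12 h and 1 lower at 24 h.

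Scaled to the same median, 17 genes had their largest difference at 1 h as higher, and 0 higher at 1 h and 1 lower at 12 h stood apart. With quantile normalization 1 lower at 12 h stood apart. With the median of all probe sets, 2 lower in vehicle, 2 higher at 1 h, 1 lower at 12 h and 0 lower at 24 h stood apart, and Krt17 at 6 h stood at -0.11. With plain probe sets alone, 2 higher and 2 lower in vehicle, 0 higher and 2 lower at 1 h and 1 lower at 24 h stood apart, and Txnip stood at 0.10, 0.29 and 0.0382 at 6, 12 and 24 h. With the mean of the vehicle and 1 h arrays as reference, Fancc on the array labelled 3 h stood at 0.0341. Without the array labelled 3 h, 9 lower in vehicle, 2 lower at 1 h, 2 higher and 7 lower at 12 h, and 9 lower at 24 h stood apart.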

Other observations

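The test on clock times was written before its value was computed, and the one on a direct effect of estradiol was chosen only after the result was seen; the clock lists were made after the values were seen. Genes that peak with Dbp, an output of the circadian clock, were low at 6 h and 12 h and near vehicle at 24 h. The 7 such genes had medians of -1.32, -1.36 and -0.31 at these times. Without Dbp and Nr1d2, the other 5, which the test on clock times used, had a median of -0.59 at 12 h. Dbp was at least 4.38-fold lower at 6 h and 12 h, Nr1d2 3.78-fold and 6.09-fold, and Tef 2.63-fold and 2.94-fold. Different clock times of sacrifice and an action of estradiol on clock genes are both possible and cannot be told apart. No clock time of sacrifice is given in the sources used here. No vehicle array is therefore known to match the 6 h and 12 h arrays in clock time. The 4 opposite-phase genes stood at 0.28 at 12 h and -0.999 at 24 h. The Dbp-phase genes stood at -0.31 at 24 h, where the interval from injection equals that of vehicle.

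Genes of the pancreatic acinar cell were highest on the vehicle array, a list made after the values were seen. The 9 genes had medians of -0.68, -1.26, -0.92, -1.05 and -0.68 at the 5 times, and 8 of them were highest in vehicle, among them Prss2, with a signal of 494 in vehicle and 43.5 or less on the others. These differences were not tested.

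Collagen and matrix genes, picked after their values were seen, went in both directions while their list stayed within the random range. Col6a3 and Col6a2 were 4.56-fold and 3.36-fold higher at 6 h, Timp1 5.21-fold higher at 12 h and Col1a1 2.81-fold higher at 24 h. Dcn was 4.02-fold and Sparcl1 4.91-fold lower at 12 h.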
